A study of Mus musculus with 4 samples.

How the data were processed

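RNA was measured in HT22, an immortalised cell line derived from mouse hippocampal neurons. The labels give HT22 as cell line and source of all 4 samples, while the titles number the cells HT22, HT23, HT24 and HT25, and all were taken as HT22. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with a stranded kit that selects polyadenylated RNA. The labels give 4 groups of cells: a control short hairpin RNA (shRNA), an shRNA against the long noncoding RNA Ntoco, an empty vector, and a vector that carries Ntoco, marked Lv. They list 1 sample per group, whereas both tables held 2 numbered columns per group, 8 columns in all. Columns were assigned to groups by the role in their names (control or targeting shRNA, vector or overexpression). The column names write the target as an abbreviation that the labels do not explain, and they name the vector pcDNA, the name of a plasmid, where the label has Lv. Whether Ntoco was raised with a plasmid or a lentivirus is therefore uncertain, and so is how the vector and shRNA controls differ in delivery. All 8 columns could be assigned by role, and 0 were left out.

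The authors deposited whole-number counts of reads per gene for 16846 genes, with no normalization. The authors also deposited FPKM values (fragments scaled by gene length and library size). In 12615 of the 12615 genes counted in all 8 libraries, the FPKM was the count divided by 1 whole-number gene length and by the sum of the listed counts, within a tolerance of 0.01. The FPKM table therefore holds the same measurements as the counts. The submitters' processing notes name Trimmomatic, HISAT2, Cufflinks, HTSeq and DESeq and the genome build mm10 (the University of California name of GRCm38). Their versions, order and roles, the gene annotation and the strand setting of the counting are not given in the sources used here. Without that setting, reads of genes that overlap on opposite strands cannot be told apart. Reads of near-identical genes, such as ribosomal protein genes and their pseudogenes, Hspa1a and Hspa1b, or Ifi202b and Ifi204, can have been split or lost in counting, so their values are uncertain.

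Of the 16846 rows, 16737 matched a gene of the GRCm38.p6 RefSeq annotation by Entrez Gene identifier. Of these, 16572 were protein-coding, 5 were long noncoding RNA genes and 158 were pseudogenes. There were 0 rows named Ntoco and 0 mitochondrial rows, and 238 rows were at 0 in all libraries. Gene coordinates are from that RefSeq annotation, 1-based, and positions in 3' untranslated regions (UTRs) are from GENCODE M21 on the same build.

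Total counts were 19172960 and 18633842 in the shRNA control libraries and 18697761 and 19401827 in the Ntoco knockdown libraries. They were 19588904 and 19622095 in the empty vector control libraries and 19859041 and 18452588 in the Ntoco overexpression libraries. At this depth counting error is small for most genes, and the spread between the libraries of a group sets the precision. Over genes with at least 100 counts in the pair, the chi-square per gene between the 2 libraries of a group was 62.1 for the shRNA control, 156 for the knockdown, 103 for the vector and 83.8 for the overexpression. A value of 1 would be counting noise alone, so the columns were used as separate libraries. The labels do not say that they came from separate cultures, so the p-values measure only the spread between these samples, which can be technical.

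Genes were filtered with edgeR's filterByExpr (minimum count 10), which left 12115, and scaled with TMM factors. The test was edgeR's quasi-likelihood F-test over all 4 groups in a single model, with 4 residual degrees of freedom, 3.85 prior degrees of freedom and a biological coefficient of variation of 28.0%. The contrasts were knockdown against shRNA control, overexpression against empty vector, and empty vector against shRNA control. A further contrast tested the difference between the overexpression and knockdown effects. P-values were adjusted by Benjamini and Hochberg over the genes tested, with a threshold of 0.05. CPM values are counts relative to library size, scaled by the TMM factors, and log2 ratios are those of the edgeR model (prior count 0.125). Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The design, the alternatives, the gene lists and the rule for naming genes were set before the data were examined, except where stated.

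There were 27 gene lists, of which 26 had measured members. They covered ferroptosis drivers, ferroptosis suppressors, iron handling, NF-kB targets and regulators, interferon-stimulated genes, hypoxia and HIF targets, NRF2 and oxidative stress response, and p53 targets. They also covered cell cycle and replication, endoplasmic reticulum stress and ATF4 targets, cholesterol and fatty acid synthesis, apoptosis, pyroptosis and necroptosis, immediate early and MAPK feedback genes, extracellular matrix and adhesion, and TGF-beta, Wnt and Notch targets. The others were neuronal and synaptic genes, heterogeneous nuclear ribonucleoproteins, heat shock and proteostasis, cytosolic ribosomal proteins, and nuclear-encoded oxidative phosphorylation subunits. Marker lists were included for astrocytes, microglia and macrophages, oligodendrocyte lineage, endothelium and pericytes, and fibroblasts and meninges. The list of mitochondrially encoded genes had 0 measured members. Lists were tested with limma's camera with a preset correlation of 0.01, again with the correlation estimated from the data, and with fry, each adjusted over the 26 lists. The KEGG pathway names that the deposited table attaches to 6624 of its genes gave 306 pathways of 10 to 300 measured members. They were tested with camera, with the preset and the estimated correlation but not with fry, and adjusted over the 306 pathways. This test was chosen after seeing the data.

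The rule for named genes took Ntoco if measured, 12 genes of the pathway in the series title, the 8 largest rises and falls past the threshold in each main comparison, the 2 to 4 members of each described list with the largest log2 ratio in size, and the 5 strongest reciprocal genes per direction. Since 0 genes passed, its parts on rises, falls and reciprocal genes named none. The 10 genes with the smallest p in each comparison, leaving out those known only by a LOC number, were added after the values were seen. Each 3' UTR 7-mer was scored by whether the genes that contain it rank lower or higher than other genes, in 11707 genes with an annotated 3' UTR. Length and base content of the UTR were held constant, and 200 permutations of the ranking were drawn. This search was also chosen after seeing the data. It was repeated on 1 knockdown minus 1 shRNA control library, with the lowest 7-mer scored in the pair of libraries left out.

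The scripts were tested on simulated counts drawn from the means and spread of the real genes, each gene independently of the others, with 200 of the 12115 genes changed in each of 5 draws per comparison. For the knockdown comparison the test recovered 8.40% of 2-fold, 74.4% of 4-fold, 88.4% of 8-fold and 95.6% of 16-fold changes, with 43 false calls over all draws. For the overexpression comparison it recovered 8.54%, 72.3%, 88.7% and 94.4% at those sizes with 30 false calls. For the control comparison it recovered 8.50%, 72.3%, 90.4% and 91.2% with 59 false calls. These rates hold for the simulated spread and do not give the share of real changes that the test would find. In the data, the 41 interferon-stimulated genes had a median log2 ratio of 4.24 in the control comparison. Of these, 40 were higher in both vector libraries, and 0 passed over all genes. A list moved by 2-fold was called in 5 of 5 draws in each comparison, with either correlation. In the data, list members moved together, with an estimated correlation of 0.40 for the NF-kB and 0.84 for the interferon list in the knockdown comparison. The simulation therefore does not show how often the test with an estimated correlation would call a moved list in these data. Other lists were called 2 times for the knockdown, 2 times for the overexpression and 1 time for the control comparison. In simulated rankings of 11707 genes, 3 of 3 planted 7-mers came out at rank 1.

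Alternatives were DESeq2's size factors, total counts in place of TMM, no filter, a stricter filter, a larger prior count, DESeq2's Wald test, only the compared groups in the model, the column number as a block, the FPKM values with limma, and leaving out each library in turn. DESeq2 gave no adjusted p for 0 knockdown, 705 overexpression and 235 control genes, which stayed without a call.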

Results

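RNA of HT22 cells, an immortalised line from mouse hippocampal neurons, was sequenced in 4 groups. Cells with an shRNA against the long noncoding RNA Ntoco were set against cells with a control shRNA, and cells overexpressing Ntoco against cells with the empty vector. The series title links Ntoco to ferroptosis, a cell death driven by iron and lipid peroxidation, and to Hnrnpab, NF-kB and Lcn2. The comparisons ask which genes and pathways differ when Ntoco is lowered or raised. Each group had 2 libraries of 18452588 to 19859041 counts, and 12115 of 16846 genes were tested. Among the rows, 0 carried the name Ntoco, so the level of the target was not measured here and the values do not check the group labels. The 2 libraries of a group differed by a median of 0.25 (log2, absolute, over genes) in the shRNA control, 0.40 in the knockdown, 0.32 in the vector and 0.25 in the overexpression group. By this measure only 2 of the 8 libraries, shRNA control library 2 and overexpression library 1, lay nearest to their own partner.

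In the knockdown, both libraries held less Tmx1, Ssx2ip, Cerk, Tbcd and Smg5 and more Txnip, C3, Ctso and C1s1 than both shRNA control libraries. Tmx1, a membrane-bound thioredoxin of the endoplasmic reticulum (Entrez Gene 72736, GRCm38 chromosome 12, 70453154 to 70467624), had 181 ± 25.1 CPM in the control and 55.8 ± 11.5 CPM in the knockdown (SD, n = 2), a log2 ratio of -1.69 (SE 0.23). Cerk, the ceramide kinase (Entrez Gene 223753, chromosome 15, 86139101 to 86186259), had 49.0 ± 2.82 and 18.7 ± 0.225 CPM, a log2 ratio of -1.39 (SE 0.20). The log2 ratio was -1.81 (SE 0.27) for the tubulin-folding factor Tbcd, -1.56 (SE 0.22) for Ssx2ip and -1.19 (SE 0.18) for Smg5, a factor of nonsense-mediated decay. It was -0.95 (SE 0.18) for the collagen chaperone Fkbp10. Txnip, which binds and inhibits thioredoxin (Entrez Gene 56338, chromosome 3, 96557957 to 96561857), had 45.3 and 49.7 CPM in the control libraries and 183 and 483 CPM in the knockdown libraries (log2 ratio 2.81, SE 0.43). The complement component C3 had 1.59 ± 0.416 and 16.9 ± 12.7 CPM (log2 ratio 3.40, SE 0.64). The protease Ctso had a log2 ratio of 2.04 (SE 0.34) and the complement protease C1s1 one of 1.73 (SE 0.33). These 10 genes were chosen after their values were seen, as those with the smallest p. The 3' UTRs of Tmx1, Ssx2ip, Cerk, Smg5 and Fkbp10 contain the sequence CTTAAGA, and those of Tbcd and Txnip do not.

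With edgeR's quasi-likelihood test, 0 of 12115 genes passed an adjusted p of 0.05 in the knockdown comparison (lowest adjusted p 0.415). At an unadjusted p under 0.05 there were 378 genes, 183 higher and 195 lower, where chance gives 606. DESeq2's Wald test called 15 genes. The 7 higher ones were Txnip, C3, Ctso, C1s1, Lbp, Angptl4 and AU041133, and the 8 lower ones were Tmx1, Ssx2ip, Tbcd, Cerk, Smg5, Myo1c, Fkbp10 and Nceh1. In edgeR 29.2% of genes had both knockdown libraries on one side of both control libraries, where chance gives 33.3%. Without knockdown library 1 the edgeR count was 1 gene, Txnip, with a log2 ratio of 3.34.

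Among the genes of the pathway in the series title, Lcn2 had a high value in 1 of the 2 knockdown libraries. Lcn2 encodes lipocalin 2, a secreted protein that binds iron-carrying siderophores (Entrez Gene 16819, chromosome 2, 32384637 to 32387739). It had 15.0 and 16.8 CPM in the shRNA control libraries, 14.3 CPM in knockdown library 1 and 907 CPM in knockdown library 2. The Lcn2 knockdown log2 ratio was 4.86 (SE 1.54, edgeR adjusted p 0.992), and it was -0.15 without knockdown library 2. Hnrnpab, an RNA-binding protein (Entrez Gene 15384, chromosome 11, 51600100 to 51606881), had 635 ± 221 CPM in the control and 546 ± 42.4 CPM in the knockdown (log2 ratio -0.22, SE 0.26). The NF-kB subunits Nfkb1 and Rela had log2 ratios of 0.58 (SE 0.30) and -0.11 (SE 0.17), and the NF-kB inhibitor Nfkbia one of 0.77 (SE 0.55). Of the ferroptosis regulators, the lipid peroxide reductase Gpx4 had 0.27 (SE 0.20), the cystine transporter Slc7a11 0.55 (SE 0.51) and the lipid ligase Acsl4 -0.02 (SE 0.18). The transferrin receptor Tfrc had -0.09 (SE 0.49), the ferritin heavy chain Fth1 0.05 (SE 0.20), the heme oxygenase Hmox1 0.15 (SE 0.31) and the cyclooxygenase Ptgs2 -1.26 (SE 0.55). None of the 12 genes passed the test.

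**Figure D1:**
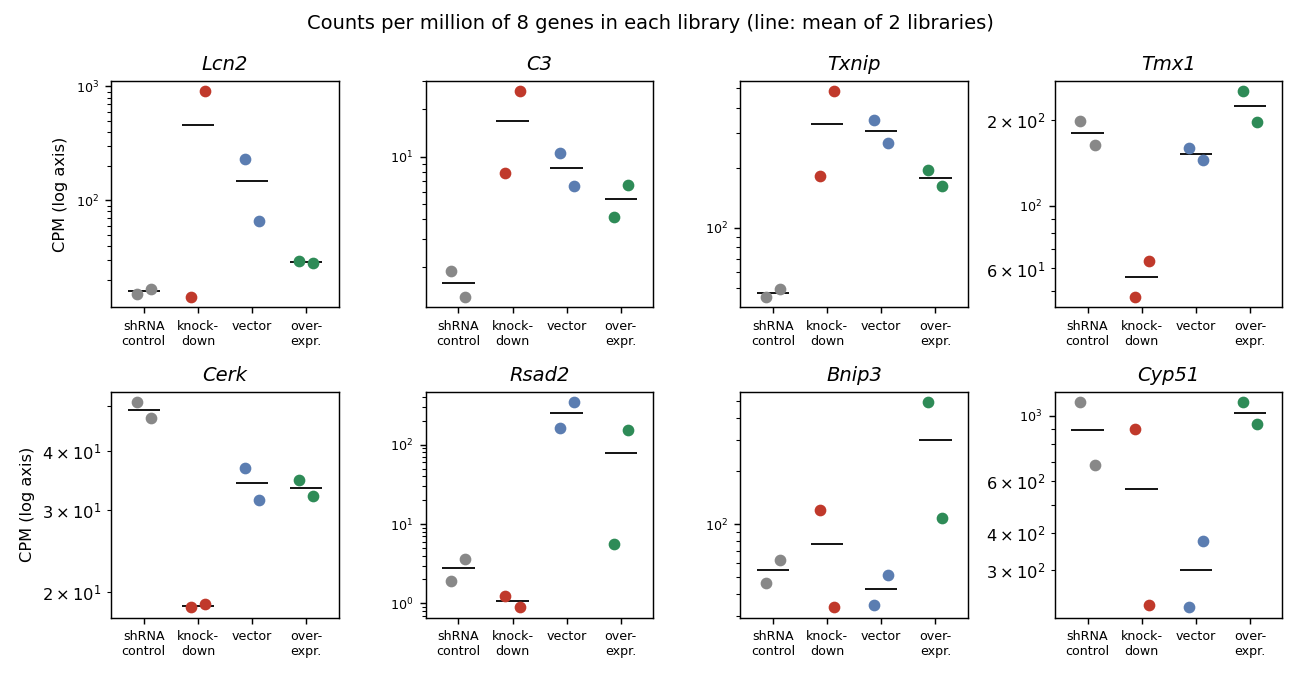
CPM (log axis) of 8 genes in each of the 8 libraries, by group; points are libraries and lines are the means of 2 libraries. Lcn2 stood at 907 CPM in 1 knockdown library and 14.3 CPM in the other, Tmx1 and Cerk lay below both control libraries in both knockdown libraries, and Rsad2 stood at 5.61 CPM in 1 overexpression library and 153 CPM in the other.

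Neither ferroptosis list was called in the knockdown. The 27 measured ferroptosis drivers had a median log2 ratio of -0.02 and the 31 suppressors one of -0.03. With p-values adjusted over the list alone, 0 drivers and 0 suppressors passed, as over all genes. The driver list had 3 members with both knockdown libraries higher and 2 with both lower, and the suppressor list 1 and 7. The largest log2 ratios among drivers were those of the metal transporter Slc39a8 (1.33) and of Ptgs2 (-1.26), and among suppressors those of Gclm (-0.87), a subunit of glutathione synthesis, and Gch1 (0.79). The 28 iron-handling genes had a median of -0.04, with Lcn2 and the ferroxidase ceruloplasmin, Cp (2.14, SE 0.63), as the largest.

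The NF-kB list was higher in the knockdown, and 1 library carried the difference. Its 45 measured members had a median log2 ratio of 0.49, with 8 members higher and 4 lower in both libraries, and camera called it (adjusted p = 0.000477). It had adjusted p = 0.881 with an estimated correlation. Over the list alone, 1 member passed, C3, against 0 over all genes. The chemokine Ccl20 had a log2 ratio of 5.45 (SE 1.71) with 1.05 CPM in knockdown library 1 and 63.6 CPM in library 2. The acute-phase gene Saa3 had one of 3.44 (SE 1.41), with 1.10 and 34.1 CPM. The chemokine Cxcl5 had 0 counts in both control libraries and in knockdown library 1, and 1.28 CPM in knockdown library 2. Relative to the shRNA control mean, the list's median was -0.20 in knockdown library 1 and 0.94 in library 2. Without library 2 the list's median was -0.24 and its direction was lower (camera adjusted p 0.00507), and without library 1 the median was 0.91.

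The cell cycle and cholesterol lists were lower in the knockdown and also rested on library 2. The 50 cell cycle and replication genes had a median log2 ratio of -0.38, with 0 members higher and 10 lower in both libraries (camera adjusted p = 8.27e-08, adjusted p = 0.881 with an estimated correlation). Examples were the transcription factor Foxm1 (-0.88, SE 0.51), cyclin D1, Ccnd1 (-0.83, SE 0.33), and the mitotic kinase Aurkb (-0.79, SE 0.54). The 32 genes of cholesterol and fatty acid synthesis had a median of -0.33 (camera adjusted p = 6.41e-05, adjusted p = 0.881 with an estimated correlation). They included the sterol demethylase Cyp51 (-0.67, SE 0.57). Over the lists alone, 0 members of either list passed, as over all genes. By library the cell cycle median was -0.05 and -0.78, and the cholesterol median 0.19 and -1.30. Without knockdown library 2 the medians were -0.07 and 0.13, without library 1 -0.80 and -1.34. Without shRNA control library 1 they were -0.14 and -0.05, and without shRNA control library 2 -0.58 and -0.64. Markers of fibroblasts and meninges differed in the same library, with medians of 0.58 in knockdown library 1 and -1.01 in library 2. Markers of endothelium and pericytes had medians of -0.41 and 0.71 there, and of 0.85 and 0.76 in the vector libraries.

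Camera called 3 further lists in the knockdown. The 41 immediate early and MAPK feedback genes were lower, with a median of -0.44 (camera adjusted p = 0.000477, adjusted p = 0.881 with an estimated correlation). Fosb (-1.64, SE 1.23) and Egr1 (-1.42, SE 1.02) had the largest log2 ratios. Egr1 had 260 CPM in shRNA control library 1 and 1683 CPM in library 2, and without shRNA control library 2 the list median was 0.31. Without shRNA control library 1 it was -0.80. Without knockdown library 2 it was -0.40 and the call was lost (camera adjusted p 0.16). The 39 endoplasmic reticulum stress and ATF4 targets were higher by a median of 0.06 (camera adjusted p = 0.0212, adjusted p = 0.923 with an estimated correlation). Fgf21 had 1.99 (SE 1.21), the stress factor Ddit3 had 1.53 (SE 0.44), and without knockdown library 2 the median was -0.08. It was 0.30 without knockdown library 1 and 0.25 without shRNA control library 2, and without shRNA control library 1 it was 0.09 with the call lost. The 55 cytosolic ribosomal protein genes were higher by a median of 0.14 (camera adjusted p = 0.00638, adjusted p = 0.923 with an estimated correlation), with 19 higher and 2 lower in both libraries. Rpl22 had 0.50 (SE 0.24) and Rpl3 0.39 (SE 0.20). The call was lost without knockdown library 1, at 0.15, and without shRNA control library 2, at 0.03, and the median was 0.25 without shRNA control library 1. Over each of the 3 lists alone, 0 members passed, as over all genes.

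Camera called none of the other 20 lists in the knockdown, and over each of them alone 0 genes passed. Median log2 ratios were 0.17 for interferon-stimulated genes, 0.06 for hypoxia targets, -0.09 for NRF2 targets and -0.05 for p53 targets. They were 0.08 for apoptosis, 0.06 for pyroptosis and necroptosis, -0.05 for extracellular matrix and adhesion, and -0.12 for TGF-beta, Wnt and Notch targets. They were -0.03 for neuronal and synaptic genes, 0.05 for oxidative phosphorylation subunits, -0.04 for heterogeneous nuclear ribonucleoproteins and -0.06 for heat shock genes. Marker medians were -0.18 for astrocytes, -0.50 for microglia and macrophages, -0.16 for the oligodendrocyte lineage, 0.28 for endothelium and pericytes, and -0.06 for fibroblasts and meninges. With limma's fry, 0 of the 26 lists were called (lowest adjusted p 0.954). Of 306 KEGG pathways, camera called 9 higher and 2 lower. Complement and coagulation cascades had the smallest adjusted p, with a median of 0.36 over 30 genes, and Cell cycle (-0.17) and DNA replication (-0.23) were lower. With an estimated correlation 0 pathways were called, with a lowest adjusted p = 0.898 with an estimated correlation.

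In the overexpression comparison, Adm, Fbxo5 and Cdca5 were higher and Atxn2, Atxn2l, Plk3, Ppp1r10, Ifi27, Bcl2l11 and Ankrd1 lower in both libraries than in both vector libraries. Adm, the hypoxia-responsive peptide adrenomedullin (Entrez Gene 11535, chromosome 7, 110627657 to 110629820), had 20.6 ± 3.03 CPM in the vector and 54.4 ± 15.7 CPM in the overexpression group (SD, n = 2), a log2 ratio of 1.40 (SE 0.28). Atxn2, an RNA-binding protein (Entrez Gene 20239, chromosome 5, 121711609 to 121814950), had 115 ± 10.2 and 57.1 ± 6.87 CPM, a log2 ratio of -1.02 (SE 0.20), and its relative Atxn2l one of -0.82 (SE 0.18). The cell cycle genes Fbxo5 and Cdca5 had log2 ratios of 1.26 (SE 0.29) and 1.31 (SE 0.31). The pro-apoptotic gene Bcl2l11 and the interferon-induced gene Ifi27 both had -1.22, with SE 0.28 and 0.27. Ppp1r10 had -1.08 (SE 0.23), Plk3 -0.88 (SE 0.19) and Ankrd1 -0.84 (SE 0.19). These 10 genes and LOC118567384, described below, had the smallest p of all and were, too, chosen after their values were seen.

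With edgeR 0 of 12115 genes passed (lowest adjusted p 0.598), and 923 genes, 428 higher and 495 lower, were at an unadjusted p under 0.05. DESeq2 called 1 gene, LOC118567384, which was lower, with 18.8 and 20.8 CPM in the vector libraries and 2.99 and 1.27 CPM in the overexpression libraries. In 47.2% of genes both overexpression libraries lay on one side of both vector libraries, where chance gives 33.3%. Without overexpression library 2, edgeR called 24 genes, all lower, of which 16 were in the interferon list. With only the 2 compared groups in the model it called 1 gene, Cfap77, which had 77.5 and 83.5 CPM in the vector libraries and 2.47 and 2.81 CPM in the overexpression libraries.

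The pathway genes of the series title did not pass the test in the overexpression comparison either. Lcn2 had 229 and 65.8 CPM in the vector libraries and 29.3 and 28.4 CPM in the overexpression libraries (log2 ratio -2.35, SE 1.38, edgeR adjusted p 0.606). The Lcn2 overexpression log2 ratio was -1.19 without vector library 1. Hnrnpab had a log2 ratio of 0.24 (SE 0.26), Nfkb1 -0.72 (SE 0.30), Rela -0.26 (SE 0.17) and Nfkbia -0.28 (SE 0.54). Gpx4 had 0.27 (SE 0.20), Slc7a11 -0.86 (SE 0.51), Acsl4 0.17 (SE 0.18) and Tfrc -0.11 (SE 0.49). Fth1 had 0.05 (SE 0.20), Hmox1 -0.05 (SE 0.31) and Ptgs2 -1.17 (SE 0.55). The ferroptosis drivers had a median log2 ratio of -0.10, the suppressors 0.17 and the iron-handling genes -0.07, with 0 members past the threshold over each list alone and over all genes, and camera called none of these lists. Among drivers the lipoxygenases Aloxe3 (-1.81, SE 0.64) and Alox15 (-1.45, SE 0.89) had the largest log2 ratios. In the suppressor list the sterol reductase Dhcr7 (1.14, SE 0.73) and the quinone reductase Nqo1 (1.06, SE 0.48) had the largest. The place of Dhcr7 in this list was fixed beforehand, and whether it suppresses or promotes ferroptosis was not tested.

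Genes of lipid synthesis and proliferation were higher in both overexpression libraries as groups under camera's preset correlation. The 32 genes of cholesterol and fatty acid synthesis had a median log2 ratio of 1.08, with 26 higher and 0 lower in both libraries (camera adjusted p = 1.30e-15, adjusted p = 0.573 with an estimated correlation). The squalene synthase Fdft1 had 2.05 (SE 0.70), Acat2 1.92 (SE 0.68), Cyp51 1.77 (SE 0.59) and the desaturase Scd2 1.59 (SE 0.90). The 50 cell cycle and replication genes had a median of 0.65, with 34 higher and 2 lower in both libraries (camera adjusted p = 8.97e-10, adjusted p = 0.573 with an estimated correlation). The mitotic genes Kif20a (1.46, SE 0.53) and Aurkb (1.07, SE 0.54) were among the largest. Over the lists alone, 0 members of either passed, as over all genes. By library, relative to the shRNA control mean, the cholesterol median was -1.62 and -0.70 in the vector libraries and 0.20 and -0.13 in the overexpression libraries. The cell cycle median was -0.58 and -0.33, and 0.15 and 0.04. The cholesterol median was 0.71 without vector library 1 and 1.64 without vector library 2.

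The hypoxia list was higher mainly in overexpression library 1. The 36 hypoxia and HIF targets had a median log2 ratio of 0.72, with 19 higher and 4 lower in both overexpression libraries (camera adjusted p = 9.07e-09, adjusted p = 0.573 with an estimated correlation). Over the list alone 1 member passed, Adm, against 0 over all genes. The mitophagy receptor Bnip3 had a log2 ratio of 2.80 (SE 0.78), with 34.6 and 51.5 CPM in the vector libraries and 490 and 108 CPM in the overexpression libraries. The HIF hydroxylase Egln3 had 2.96 (SE 1.12), Ankrd37 2.43 (SE 0.72) and the lactate transporter Slc16a3 3.66 (SE 1.46). By library the list median was 1.08 in overexpression library 1 and 0.08 in library 2, relative to the shRNA control mean. Without library 1 the median against the vector was 0.18 and the call was lost.

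The interferon list was lower in the overexpression comparison, and 1 library carried the difference. The 41 interferon-stimulated genes had a median log2 ratio of -0.80, with 0 higher and 12 lower in both libraries (camera adjusted p = 3.70e-11, adjusted p = 0.573 with an estimated correlation). Rsad2, an antiviral enzyme, had 164 and 346 CPM in the vector libraries and 5.61 and 153 CPM in the overexpression libraries (log2 ratio -1.69, SE 1.11), and the RNA sensor Oas2 had a log2 ratio of -1.42 (SE 1.34). By library the median was 4.16 and 4.55 in the vector libraries, 0.71 in overexpression library 1 and 4.51 in library 2. Without library 2 the median against the vector was -3.83, and without library 1 it was -0.03 and the call was lost (camera adjusted p 0.666). Over the list alone, 0 genes passed, as over all genes.

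The NF-kB list was lower as well, with a median log2 ratio of -0.65 and 2 members higher and 22 lower in both libraries (camera adjusted p = 2.04e-05, adjusted p = 0.573 with an estimated correlation). By library, relative to the shRNA control mean, its median was 1.06 and 1.57 in the vector libraries and 0.59 and 0.37 in the overexpression libraries. The list was thus lower than in the vector libraries but not lower than in the shRNA control. Cxcl5 had 0.642 and 0.0515 CPM in the vector libraries and 0.0515 and 0 CPM in the overexpression libraries. Lcn2, the chemokine Cxcl10 (-2.24, SE 1.13) and the cytokine Csf2 (-2.16, SE 1.25) followed. Without vector library 2 the list's median was -0.29 and the call was lost (camera adjusted p 0.0780). The 39 endoplasmic reticulum stress and ATF4 targets had a median of -0.44, with 0 higher and 17 lower in both libraries (camera adjusted p = 2.12e-05, adjusted p = 0.573 with an estimated correlation). Fgf21 had -2.30 (SE 1.22) and Ppp1r15a -1.33 (SE 0.74). This call was lost without vector library 1, with a median of -0.09, and without overexpression library 2, with -0.27. Relative to the shRNA control mean, the median of this stress list was 0.83 and 0.19 in the vector libraries. It was 0.30 and 0.01 in the overexpression libraries, so not lower than in the shRNA control. The immediate early list had a median of -0.36 (camera adjusted p = 0.00304, adjusted p = 0.573 with an estimated correlation), with Nr4a2 at -1.28 (SE 0.33) and Ccn1 at -1.21 (SE 0.73). Its call was lost without vector library 2, at -0.03, and without overexpression library 2, at -0.26, and the median was -0.64 without overexpression library 1. Over each of the 3 lists alone, 0 genes passed, as over all genes.

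Smaller shifts were higher values of 3 lists. The NRF2 and oxidative stress list had a median log2 ratio of 0.31, with 15 higher and 3 lower in both libraries (camera adjusted p = 0.000485, adjusted p = 0.573 with an estimated correlation). It included the pentose phosphate enzyme Pgd (1.07, SE 0.39) and Nqo1. The median was 0.16 without vector library 1 and 0.47 without vector library 2. Relative to the shRNA control mean, the NRF2 median was -0.38 and -0.21 in the vector libraries and 0.11 and -0.04 in the overexpression libraries. The overexpression values thus lay within those of the shRNA control libraries (0.12 and -0.12), and the vector values below them. The ribosomal protein list had a median of 0.26, with 38 higher and 0 lower (camera adjusted p = 1.55e-07, adjusted p = 0.573 with an estimated correlation), Rpl7 at 0.73 (SE 0.19) and Rpl4 at 0.72 (SE 0.22). Without vector library 2 its median was 0.17. The oxidative phosphorylation subunits had a median of 0.26, with 30 higher and 0 lower (camera adjusted p = 1.48e-06, adjusted p = 0.573 with an estimated correlation), Ndufa8 at 0.83 (SE 0.29) and Ndufb5 at 0.74 (SE 0.26). Without overexpression library 1 their median was 0.16. Over each of the 3 lists alone, 0 genes passed, as over all genes. Reads of ribosomal protein genes can be shared with their pseudogenes, so single values are uncertain.

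Camera called none of the other 16 lists in the overexpression comparison. Median log2 ratios were -0.34 for p53 targets, 0.06 for apoptosis, 0.03 for pyroptosis and necroptosis, 0.01 for extracellular matrix and adhesion, and -0.16 for TGF-beta, Wnt and Notch targets. They were -0.10 for neuronal and synaptic genes, -0.03 for heterogeneous nuclear ribonucleoproteins and -0.05 for heat shock genes. Marker medians were 0.24 for astrocytes, 0.07 for microglia and macrophages, -0.07 for the oligodendrocyte lineage, -0.96 for endothelium and pericytes and 0.29 for fibroblasts and meninges. Over the lists alone 1 of these genes passed, Plk3 in the p53 list, against 0 over all genes. With limma's fry, 0 of the 26 lists were called (lowest adjusted p 0.391). Of 306 KEGG pathways, camera called 40 higher and 8 lower, and 0 with an estimated correlation (lowest adjusted p = 0.696 with an estimated correlation). Higher pathways included Ribosome (median 0.24), DNA replication (0.42), Proteasome (0.33), Glycolysis / Gluconeogenesis (0.45) and Steroid biosynthesis (0.72). Complement and coagulation cascades was lower, with a median of -0.43.

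**Figure D2:**
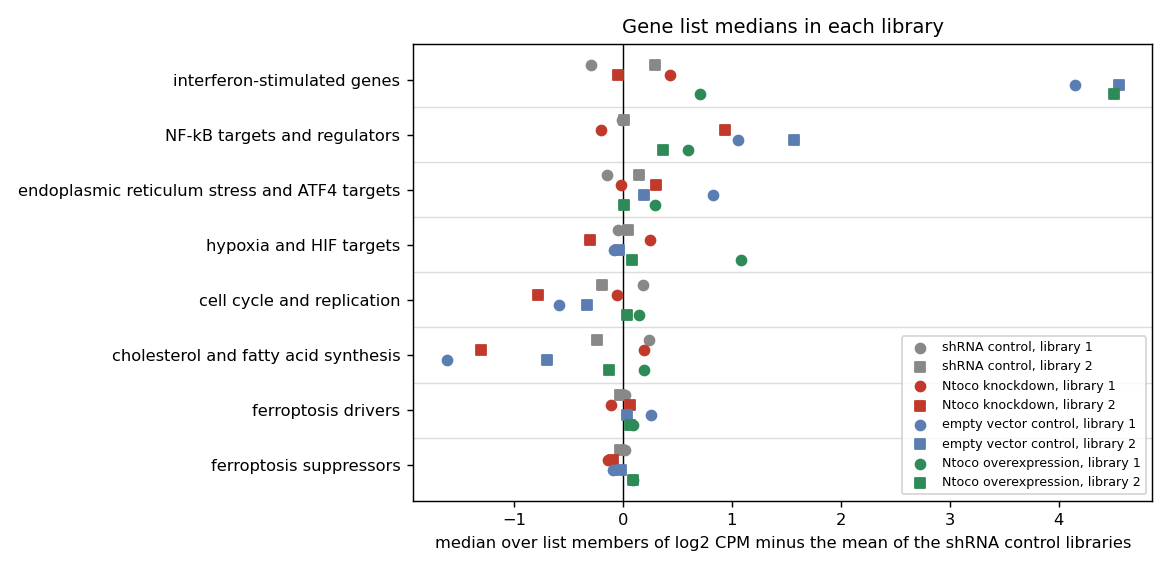
Median over the measured members of 8 gene lists of the log2 CPM in each library minus the mean of the shRNA control libraries (horizontal axis), with 1 point per library; circles are library 1 and squares library 2 of a group. The interferon list lay at 4.16, 4.55 and 4.51 in both vector libraries and overexpression library 2 and between -0.30 and 0.71 in the other libraries, and the ferroptosis lists lay near 0 in all 8.

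The vector and shRNA controls were compared because neither has Ntoco changed. The vector libraries held far more RNA of interferon-stimulated genes. The 41 list members had a median log2 ratio of 4.24, and 40 of them were higher in both vector libraries than in both shRNA control libraries (camera adjusted p = 3.90e-57, adjusted p = 0.644 with an estimated correlation). Rsad2 had 1.94 and 3.58 CPM in the shRNA control and 164 and 346 CPM in the vector libraries, a log2 ratio of 6.53 (SE 1.40). Usp18 had 6.31 (SE 1.53), Ifit1 6.23 (SE 1.56) and Ifi44 6.19 (SE 1.63), and Irf9, a subunit of the interferon-activated transcription factor, had 4.12 (SE 0.64). Over the list alone 40 genes passed, against 0 over all genes. The NF-kB list had a median of 1.38, with 34 of 45 members higher and 0 lower in both libraries (camera adjusted p = 1.78e-15, adjusted p = 0.644 with an estimated correlation). Over the list alone 8 members passed. Its largest log2 ratios were those of Cxcl10 (6.71, SE 1.44) and Ccl5 (6.13, SE 1.45), and Lcn2 had 3.21 (SE 1.43).

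Other groups also differed between the controls. The cholesterol and fatty acid synthesis list had a median log2 ratio of -1.18, with 28 of 32 members lower in both vector libraries (camera adjusted p = 8.14e-12, adjusted p = 0.644 with an estimated correlation) and Fdft1 at -1.96 (SE 0.70). The median was -0.74 without vector library 1. The cell cycle list had a median of -0.51 (camera adjusted p = 5.61e-06, adjusted p = 0.644 with an estimated correlation), with Aurkb at -1.54 (SE 0.55) and Kif20a at -1.45 (SE 0.53). Without shRNA control library 1 it was -0.28 and the call was lost, and without shRNA control library 2 it was -0.78. The endoplasmic reticulum stress list had a median of 0.55 (camera adjusted p = 1.01e-07, adjusted p = 0.644 with an estimated correlation), with Fgf21 at 2.34 (SE 1.23) and Slc7a11 at 1.47 (SE 0.52). Without vector library 1 it was 0.12. The NRF2 list (-0.32, camera adjusted p = 0.0255, adjusted p = 0.644 with an estimated correlation) lost its call without shRNA control library 1, at -0.22, or vector library 1, at -0.21. The markers of fibroblasts and meninges (-0.94, camera adjusted p = 0.0404, adjusted p = 0.644 with an estimated correlation) and the ribosomal proteins (0.14, camera adjusted p = 0.0404, adjusted p = 0.840 with an estimated correlation) lost theirs without vector library 1, at -0.61 and 0.07, or without either overexpression library, at -0.94 and 0.14. The markers also lost it without shRNA control library 1, at -0.80, and their median was -1.42 without vector library 2. The ribosomal list also lost it without shRNA control library 2, at 0.03, or without either knockdown library, at 0.14, and its median was 0.29 without shRNA control library 1 and 0.26 without vector library 2. Col3a1 had -2.01 (SE 1.41) and Rpl4 -0.56 (SE 0.22). Over these 6 lists alone, 0 genes passed, as over all genes. Outside the called lists, 1 gene passed over its list alone in each of 2 lists, Klf10 among the immediate early genes and Mmp2 among the matrix genes.

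The genes with the smallest p in the control comparison, chosen after their values were seen, were led by Ifi27, with 40.0 ± 4.32 CPM in the shRNA control and 260 ± 48.0 CPM in the vector libraries (log2 ratio 2.70, SE 0.28). The HIF hydroxylase Egln2 was at -1.49 (SE 0.20), Irf9 at 4.12, and Txnip, which was also higher in both knockdown libraries, at 2.68 (SE 0.43). Both Txnip ratios rest on the same shRNA control libraries. With edgeR 0 of 12115 genes passed (lowest adjusted p 0.159), and 1520 genes were at an unadjusted p under 0.05. DESeq2 called 281 genes, 198 higher and 83 lower, of which 36 were in the interferon list. In edgeR, leaving out overexpression library 1 gave 97 called genes and leaving out overexpression library 2 gave 96, with 36 in the interferon list each time. The overexpression libraries take no part in this contrast, but they add to the estimate of the spread, to which their interferon values contribute. With only the 2 control groups in the model, edgeR called 130 genes, 120 higher and 10 lower, 37 of them in the interferon list. With limma's fry, 0 of the 26 lists were called (lowest adjusted p 0.400). Of 306 KEGG pathways camera called 21 higher and 11 lower, among them Antigen processing and presentation (median 0.46) and NOD-like receptor signaling (0.16), and 0 with an estimated correlation (lowest adjusted p = 0.680 with an estimated correlation).

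Knockdown and overexpression were also set against each other, since a gene that follows Ntoco would move in opposite directions. Across 12115 genes their log2 ratios correlated with a Pearson r of -0.25 and a Spearman rho of -0.20, and the comparisons share no library. Genes are not independent replicates, so no p is given. The r was -0.52 without knockdown library 1 and 0.34 without knockdown library 2. With edgeR 0 genes passed in both comparisons. At an unadjusted p under 0.05 in both, 11 genes were lower in the knockdown and higher in the overexpression, where 6.89 were expected of independent lists, and 4 went the other way, where 7.48 were expected. A further 2 were higher in both, where 6.47 were expected, and 5 lower in both, where 7.97 were expected. Of the genes with separated libraries in both comparisons, 440 were lower and then higher (413 expected), 351 higher and then lower (423 expected), 328 higher in both (440 expected) and 329 lower in both (396 expected). The test of the difference between the overexpression and knockdown effects called 0 genes (lowest adjusted p 0.650, 838 genes at an unadjusted p under 0.05). DESeq2 also called 0 genes in both comparisons in opposite directions.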

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

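The lists without seed-site genes and the KEGG test were chosen after results were seen, the other settings before. In edgeR 0 genes passed in the knockdown and overexpression comparisons under other scalings, filters, prior count and FPKM values with limma. Without a filter the control comparison had 3 genes (Ifi27, Ifi202b and Irf9) against 0 with it. With only the 2 compared groups in the model it had 130 and the overexpression comparison 1. DESeq2's Wald test called 15 genes in the knockdown, 1 in the overexpression and 281 in the control comparison, where edgeR called 0 each time. The cause was not tested. With each library left out in turn the counts ranged from 0 to 1 in the knockdown, the 1 without knockdown library 1, from 0 to 24 in the overexpression and from 0 to 97 in the control comparison. The 24 came without overexpression library 2, the 97 without overexpression library 1, and 96 without overexpression library 2. A group left with 1 library was taken to vary like the others.

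Camera called 6 lists in the knockdown, 10 in the overexpression and 8 in the control comparison, and 0, 0 and 0 with the correlation estimated from the data. Over the other settings the numbers ranged from 5 to 8, 8 to 12 and 6 to 12. Without the genes that hold CTTAAGA or TTAAGAA they were 5, 11 and 9. With a library left out, 4 knockdown lists turned direction, and the cause was not tested. The NF-kB median ranged from -0.24 to 0.91, the endoplasmic reticulum stress and ATF4 median from -0.0799 to 0.30 and the cholesterol median from -1.34 to 0.13, with knockdown library 2 and then library 1 left out or the reverse. The immediate early median ranged from -0.80 to 0.31, without shRNA control library 1 and library 2. The correlation of knockdown and overexpression was -0.52 without knockdown library 1, 0.34 without knockdown library 2, -0.09 without a filter, and -0.24 to -0.27 under the other settings with all libraries.

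The column number was also used as a replicate block. The edgeR counts stayed at 0 in all 3 comparisons, the lists called were 7, 10 and 8, and the correlation was -0.27. Same-numbered libraries deviated from their group means with correlations of -0.36 to 0.36, so the numbers were not taken to pair the samples. Of 2006 log2 ratios of 231 single-gene results recomputed under 9 settings, 1997 moved by less than 1 SE and 4 took the other sign. Of 1848 with a library left out, 1647 moved by less than 1 SE and 67 took the other sign. Alternatives planned for groups with 1 library were not run, since each group had 2. Depth limits genes with few counts, such as Cxcl5, with 0 counts in both shRNA control libraries.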

Other observations

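Some members of lists that were not called had large log2 ratios in the knockdown and in the vector libraries alike. The death receptor Fas had a log2 ratio of 2.59 in the knockdown and 1.92 in the control comparison, the protease inhibitor Timp3 2.31 and 3.80, and the adhesion molecule Nrcam 2.29 and 2.67. In the overexpression comparison Timp3 had -2.27 and Nrcam -2.63. In the control comparison the nucleic acid sensors Zbp1, which is also in the called interferon list, and Tlr3 had 5.58 and 2.18. The knockdown values of Fas, Timp3 and Nrcam rest on library 2, with 1.94, 1.10 and 0.366 CPM in library 1 and 16.3, 8.73 and 3.75 CPM in library 2. None of these genes passed edgeR's adjusted p of 0.05. The knockdown and control comparisons share the shRNA control libraries, and the overexpression and control comparisons share the vector libraries. The ratios of a gene across these comparisons are therefore not independent.

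The heat shock gene Hspa1b varied within groups, with 28.0 and 0.670 CPM in the vector libraries and 1.03 and 17.6 CPM in the overexpression libraries. In the overexpression comparison the lowest-ranked 7-mer of the 3' UTR was TATTTAT (z -7.33, lowest of 200 permutations -5.17).

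In the patterns below, the tests of a turn-around and of a label exchange by the raw CTTAAGAA difference were written before their values were seen. The tests of seed silencing, with length and composition of the 3' UTR held, of base composition, of the interferon pattern, of immune cells and of seed-matched genes alone were chosen after results were seen. Of all 11707 genes with a 3' UTR, 23.4% hold a site, CTTAAGA or TTAAGAA. Among genes with the smallest p in the knockdown, 8 of the 10 lower and 0 of the 10 higher ones hold a site. The numbers were 57 of the 100 lower and 12 of the 100 higher ones. Genes with CTTAAGA in the 3' UTR were lower in the knockdown (z -12.6, lowest of 200 permutations -4.95). A seed match of the shRNA could account for this, but CTTAAGA was found in these same libraries: chosen as the lowest 7-mer of knockdown library 1 against either shRNA control library, it had a z of -4.13 and -2.69 in the pair left out (ranks 4 and 114 of 16384), while the lowest 7-mers of library 2, ATCTCAC and CGAGCTG, had 1.97 and -0.0140, so the test leaves it open. Other 7-mers of the same bases, leaving out those that share 6 bases in a row with the site, reached a z of -3.75. This is no separate test of base composition, since length and base content were already held in every z. CTTAAGA was also picked as the lowest of all 7-mers. CTTAAGAA genes were at -0.0891 (SE 0.0237) in overexpression against vector. With length and composition of the 3' UTR held they were at 0.0114 (SE 0.0278), against -0.242 (SE 0.0241) in the knockdown, and both values lie below a turn-around of 0.5 times the fall in the knockdown. These means do not speak for each gene, and their SEs are over genes, not over libraries. Tmx1 and Smg5 were higher in overexpression against vector, with log2 ratios of 0.56 and 0.51. They were among the 11 genes lower in the knockdown and higher in the overexpression at an unadjusted edgeR p under 0.05, where 6.89 were expected. Cerk, Ssx2ip and Fkbp10 were not among these. The shRNA sequence was not used here, so whether Tmx1, Cerk, Ssx2ip, Smg5 and Fkbp10 are lower through the shRNA itself stays open.

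Interferon-stimulated genes were low in overexpression library 1 and high in overexpression library 2 and both vector libraries. An exchange of labels with an shRNA library would leave a high shRNA library, but the gap between the lowest high library and the highest shRNA library was 3.72. For RNA of immune cells, the 6 immune markers below the filter were used, among them Ptprc and C1qa with 0 counts in all libraries. At the smallest share of such cells that gives the gain of the list, these markers would average at most 8.94 CPM in them. A tested gene averages 82.5 CPM. The markers were taken for their few counts in these libraries, and their level in immune cells was not measured, so the limit does not exclude such cells. Of the 7 measured markers, 3 were higher and 4 lower in the 3 high libraries than in overexpression library 1. A library of another group under this label stays open: 0 libraries of other groups lay nearer to it than its partner, but only 2 of 8 libraries lay nearest to their partner. A response to the vector or to its delivery, or an effect of Ntoco on it, was not tested.

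Lcn2 and NF-kB targets were high in knockdown library 2 and not in library 1, with Lcn2 63.5-fold higher in library 2. For an exchange of labels with a vector library, the test written first, with the raw CTTAAGAA difference of -0.107 in library 2, did not pass its bound. A second test, written after that, held length and composition of the 3' UTR. It gave -0.198 (SE 0.0335) in library 2, against -0.0370 and -0.0663 in the vector libraries. These SEs are over genes and do not measure the spread between libraries. Between the 2 shRNA control libraries the raw difference was -0.0663 (SE 0.0231), and -0.0222 (SE 0.0269) with length and composition held. The second test leans against an exchange, without a measure of that spread. It has the further limit that CTTAAGA was found in libraries that included library 2. Going the other way, library 2 lay nearest to vector library 1 (median absolute log2 difference 0.302, against 0.402 to its partner). However, only 2 of 8 libraries lay nearest to their partner. By the interferon list, library 2 was unlike both vector libraries, with a median of -0.04 against 4.16 and 4.55, and 0.44 in library 1. This list also differed within the overexpression group (0.71 and 4.51), so it does not settle the label alone. For RNA of immune cells, the 6 markers would average at most 23.2 CPM in such cells for the gain of the NF-kB list. The limit was 84.3 CPM for the gain of Lcn2 alone, and a tested gene averages 82.5 CPM. As above, the level of these markers in immune cells was not measured, so immune cells stay open for both. Of the 7 measured markers, 4 were higher and 3 lower in library 2 than in library 1. Silencing of seed-matched genes alone would be shared by both libraries, but the NF-kB list median was -0.197 in library 1 and 0.942 in library 2. The same holds for loss of Ntoco alone. The values argue against either as the only cause, if it acted equally in both libraries. The level of Ntoco was not measured, so it may have differed between them. What raised Lcn2 in library 2 stays open, including an uncontrolled difference between the libraries.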
